A study of Mus musculus with 10 samples.

How the data were processed

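RNA was measured on 10 single-colour Affymetrix arrays, 5 of Jam2+ and 5 of Jam2- haematopoietic stem cells (HSCs) of mice, sorted as CD150+ CD48- c-Kit+ Sca-1+ cells without lineage markers. Per the labels, the cells came from 5 male mice, the RNA was isolated with a micro-scale column kit, and the cDNA fragments were end-labelled with biotin. The deposited values are on a log2 scale, 1 value per row and array for 41345 rows. The submitters' processing notes name the R package oligo, and its version, the background correction and the normalization are not given in the sources used here. The array medians lay between 5.96 and 6.05, so the arrays were on a common scale. Whether values were centred per gene was not stated; row means ran over the whole intensity range, so they were not. Arrays give no read depth, and the number of arrays limits the precision.

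A table pairing row IDs with the platform's annotation gave 1 gene symbol for 23521 rows, several for 1814 and none for 16010. Of the rows with 1 symbol, 23328 had their Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, and 0 of those symbols differed. Rows with 1 symbol were tested, with the brightest row standing for its gene, which left 22180 genes and no filter on dim rows.

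The groups were compared with limma's lmFit and eBayes, with the group as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Single values were also compared by an exact two-sided permutation test over the 252 assignments of 5 arrays against 5, whose smallest p is 0.00794. A set of 27 gene lists covering blood lineages, stem cell identity, Notch and TGF-beta signalling, cell cycle, metabolism, stress, adhesion and other marrow cells was tested with camera at a preset inter-gene correlation of 0.01, for lists with at least 5 measured genes. Olfactory receptors were included as a family that blood stem cells are not known to use. The test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. That rule named up to 10 genes per direction, by adjusted and then unadjusted p among genes with informative symbols, together with Jam2, its relatives, the genes of the sort, Notch and lymphoid genes, and members of called lists. It was applied, but because the gene names were not borne out by the values, rows are given by ID and at most 2 per direction are printed.

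Whether the row IDs go with the values was checked in 3 ways, all chosen after the values had been seen. The levels of rows were compared between gene families, rows with identical values on all arrays were compared by gene, and the step from each ID to the next was set against the row mean at other offsets. A hidden Markov model then placed IDs on displaced rows from the ID steps, the presence of any gene name, and the row's mean and spread. On 12000 rows simulated from the model's own tables and settings it placed 42.8% above a posterior of 0.9, and 98.7% of these exactly. Such rows meet the model's assumptions, so these shares do not measure its accuracy on the real rows. The model's tables were re-estimated from its own placements, so its posteriors may be too high on the real rows. Other placements were tried before it: a single circular offset, family levels in windows, ID steps in windows of 300 rows, and a best single path, which is kept as an alternative. The offset was first seen from family levels, so those levels are not independent of its discovery. Its value was then set from the ID steps in windows, so those steps are no independent test of it. Results on displaced rows appear only among the additional observations.

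The limma procedure was tested on simulated data with 200 changed genes among 22180 in 20 simulations. It recovered 34.5% of differences of 0.5, 83.2% of differences of 1 and 96.9% of differences of 2 on the log2 scale, with 7.6 false calls on average. The sizes were mixed among the changed genes, so these shares hold where many genes change at once. They do not give the chance of finding a lone change. Alternatives were the replicate number as a block, each array left out, other variance models, array weights, filters on dim rows, 3 rescalings, other summaries per gene, all rows, an unmoderated statistic, a threshold of 0.1, and other list tests. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.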

Results

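Gene expression was measured in mouse HSCs with and without the surface protein Jam2, a junctional adhesion molecule of the immunoglobulin family. Each of the 2 groups held 5 arrays, numbered 1, 2, 4, 5 and 6 in both. The labels state that the cells came from 5 mice and do not say that a number stands for a mouse. The p-values therefore measure the spread between these arrays. With 10 arrays from 5 mice, the arrays do not stand for separate animals. The main fit and the exact permutation test treat all 10 as independent, so their p-values do not allow for shared mice. Pearson's r between arrays across all 41345 rows ran from 0.958 to 0.984; it is a correlation across rows, which are not independent replicates.

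Arrays Jam2+ replicate 1 and Jam2- replicate 6 stood apart, with mean r with the other arrays of 0.970 and 0.968. The remaining 8 arrays lay between 0.976 and 0.980. The first 3 principal components held 20.8%, 14.4% and 10.9% of the variance. The groups did not differ on the first (exact permutation p = 0.484) or second (exact permutation p = 0.754); on the third the exact permutation p was 0.0317, unadjusted for the 3 components tested, and Jam2+ replicate 2 lay farthest out there.

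**Figure D1:**
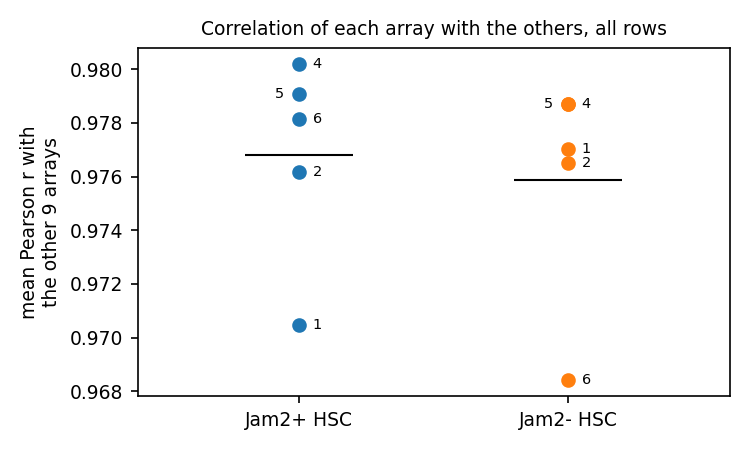
Mean Pearson r of each array with the other 9 arrays over all rows (vertical axis, no unit) for each group; points are arrays with their replicate numbers and lines are group means. Jam2+ replicate 1 at 0.970 and Jam2- replicate 6 at 0.968 lie below the other arrays.

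Row identity was examined before any gene was named, because the levels of familiar genes did not go with their names. Rows paired with ribosomal proteins, which growing and resting cells make in abundance, had a median of 5.87 over 90 rows. Rows paired with olfactory and vomeronasal receptors, sensory genes that blood cells are not known to use, had a median of 5.94 over 1383 rows. NADH dehydrogenase, proteasome and splicing genes had a median of 5.94, and keratins and beta-defensins 5.98. The row paired with Kit, the receptor used in the sort, had a mean of 2.85, with 3.67% of rows below it. B2m, the light chain of MHC class I, had 3.42 and Ptprc, the pan-leukocyte antigen CD45, had 4.48. Xist, the RNA of the inactive X chromosome in females, had 9.35, although the mice were male. Of the Y-linked genes examined, Eif2s3y had 2.94 and Uty 3.83, while Kdm5d had 8.57, with 86.5% of rows below it. Among 158 pairs of rows with identical values on all arrays and 1 gene each, 0 pairs had the same gene. The arrays resembled each other closely, so rows carried reproducible values whose gene names were not borne out. No gene is therefore reported as higher or lower here, and symbols below say only which name an ID is paired with.

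**Figure D2:**
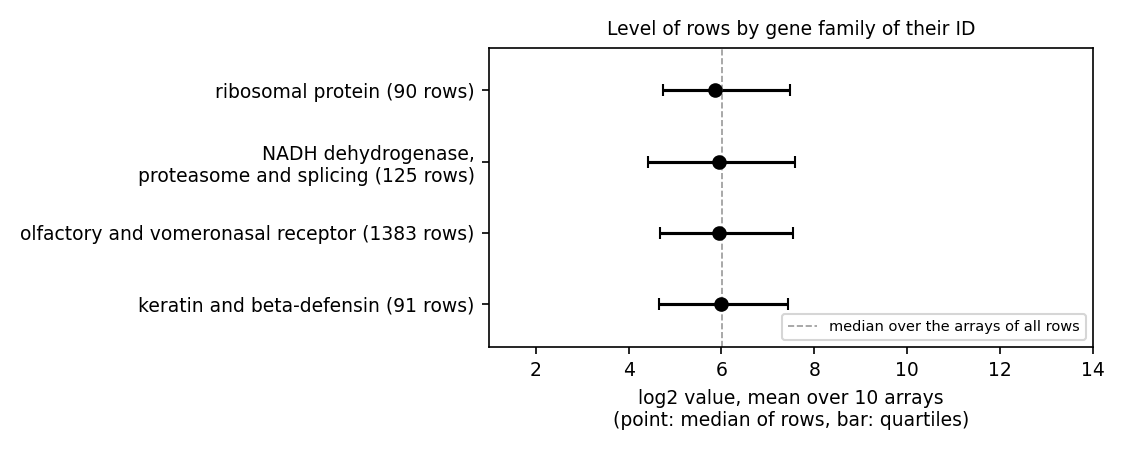
Level of rows grouped by the gene family of their ID, as deposited; the horizontal axis is the log2 value averaged over 10 arrays, points are medians of rows, bars run between the quartiles and the dashed line is the median of all rows, taken as the middle of the array medians. The medians of the 4 families lie between 5.87 and 5.98.

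The comparison of Jam2+ with Jam2- HSCs asks how the transcriptomes of the sorted populations differ. Jam2 was the sorting criterion and so a check of the labels. The row paired with Jam2 had a log2 value of 5.07 ± 0.12 (SD, n = 5) in Jam2+ HSCs and 4.98 ± 0.09 (SD, n = 5) in Jam2- HSCs. The difference was 0.09 with a standard error of 0.081 (limma adjusted p = 0.997), and the exact permutation p was 0.214. Since its name was not borne out, this row neither supports nor contradicts the sort. Rows paired with the other 12 fixed genes that had a row, among them F11r, Jam3, Slamf1, Cd48, Kit, Notch1, Hes1 and Flt3, differed by -0.29 to 0.07, with a smallest limma adjusted p of 0.997. Ly6a, which encodes Sca-1, had no row with a single symbol.

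Of 22180 gene rows, 0 were higher and 0 lower in Jam2+ HSCs in limma, and the smallest adjusted p was 0.347. At an unadjusted p under 0.05 there were 958 rows, 540 higher and 418 lower, where chance gives 1109. Among all 41345 rows, 0 passed and 1688 had an unadjusted p under 0.05, where chance gives 2067. These counts do not depend on which gene a row stands for, apart from the choice of rows tested. Point estimates exceeded 1 in 72 rows and were below -1 in 32, and ran from -2.01 to 2.01. The median standard error was 0.121 and its 90th percentile 0.292.

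Row 17250093 had the smallest p. It was 8.60 ± 0.29 (SD, n = 5) in Jam2+ and 7.43 ± 0.23 (SD, n = 5) in Jam2- HSCs, a difference of 1.17 with a standard error of 0.155, and was higher in all 5 same-numbered pairs. Its limma adjusted p of 0.347 did not pass. Row 17516243 followed with a difference of 0.98 (limma adjusted p = 0.997); without Jam2+ replicate 6 it passed, with a difference of 1.17 and a limma adjusted p of 0.0289. Rows 17270703 and 17290629 had the smallest p among lower rows, with differences of -0.35 and -0.42 (limma adjusted p = 0.997 for both). These 4 rows were picked by p, so their sizes tend to be overstated.

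**Figure D3:**
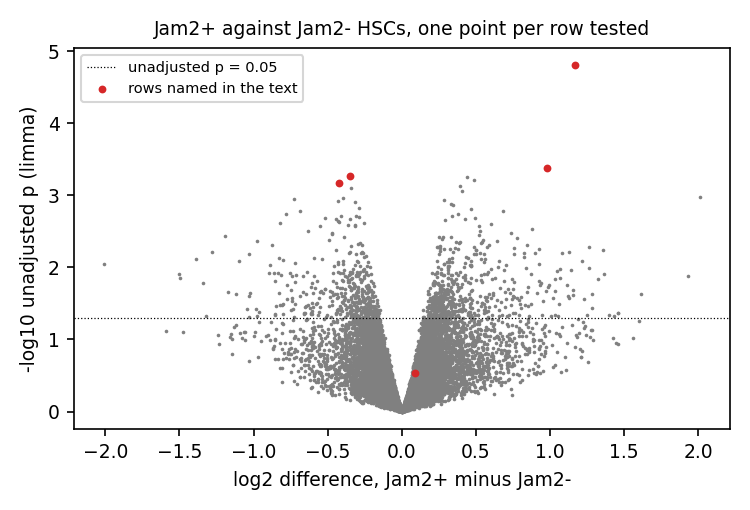
Log2 difference of Jam2+ minus Jam2- HSCs (horizontal axis) against the negative log10 of the unadjusted limma p (vertical axis), with 1 point for each of the 22180 rows tested. Red points are the row paired with Jam2 and the 4 rows given by ID; row 17250093 lies at 1.17, and no row passed after adjustment.

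With the names as given, camera called 0 of 27 gene lists, and the smallest adjusted p was 0.20. List means differed by -0.12 to 0.10. Lists of stress response, long-term HSC and Hox genes had an unadjusted p under 0.05. The self-contained test fry called 1 list, Hox genes, at an adjusted p of 0.04998 with a mean difference of 0.06. For that list the adjusted p was 0.289 in camera with an estimated correlation and 0.714 in the exact permutation test. Of all list members, 0 passed over all genes, and 2 passed adjusted over the list alone. As list membership rests on the names, these values describe sets of rows and not gene groups.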

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

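All tests of explanations in this part were chosen after the results were seen. Of 22 groups of 5 arrays tested for an outlying value, 2 held one, where chance gives about 1.1. Jam2- replicate 6 had a mean correlation with the other arrays of 0.968, against 0.977 for the nearest array of its group. With rows displaced as described among the other observations, the G2/M list mean of Jam2+ replicate 5 was 8.76, against 8.23 for the nearest array of its group.

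Gene names and values did not go together, as the levels of ribosomal protein and receptor rows show. Arrays without gene signal are argued against: in the last 5562 IDs, with rows displaced by 5562 places, ribosomal protein rows lay 8.53 above receptor rows on the log2 scale. The offset was first seen from such levels, so a gap above those at other offsets was favoured in advance. Only its size argues here, as the same IDs reached at most 4.07 at the 41344 other offsets. A faulty gene table alone would leave the step between IDs, which the value table itself holds, tied to the row mean in place. That rank correlation was 0.0274, below the highest of 1000 other offsets, 0.120. The test presumes that steps go with row means in an ordered table. Such a link was seen only at the offset set from those steps, so the test by itself does not decide. A displacement of values against IDs may be the cause: at the offset of 5562 the correlation was 0.213. That offset was itself set as the most frequent best fit of ID steps in windows. Its lead over the 1000 other offsets was therefore favoured in advance and is no independent test. Whether it arose before or after deposit stays open, and no biological explanation was tested.

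Chance cannot be excluded for the count of unadjusted calls between the groups: of 100 splits of the 10 arrays, the real one included, 58 gave at least its 958, and the highest other gave 1868. For genes past the threshold the splits decide nothing, since the real split called 0 and all 100 give at least that; the highest other called 2.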

How the results depend on the processing

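The runs without both Jam2+ replicate 1 and Jam2- replicate 6, and those on displaced rows, were chosen after the data were seen. The count of lower genes was 0 under 29 of 29 alternatives and that of higher genes under 28 of 29; leaving out 1 array at a time gave 0 to 1 higher genes, the 1 without Jam2+ replicate 6 (row 17516243, adjusted p = 0.0289, with 0.0289 to 1.00 over its alternatives). On that row Jam2+ replicate 6 had 5.60, against 6.36 to 6.78 in the other Jam2+ arrays and 5.26 to 5.53 in Jam2- arrays. Leaving it out therefore raised the difference and narrowed the spread. Why that array was lower was not tested. Unadjusted calls were 881 to 1067 with 1 array left out, 536 with the lowest 50% of rows by mean removed and 1688 over all rows, as fewer or more rows were tested. The lists called rose from 0 to 1 with the lowest 25% removed, to 1 with the lowest 50% removed and to 1 with fry; the cause was not tested. The row paired with Jam2 kept its direction and missed the threshold under 25 of 25 alternatives, with differences of 0.04 to 0.16; it had no value with the lowest 50% removed. With the replicate number as a block, 0 genes were higher, 0 lower, and 0 lists were called; camera takes no random block. Deviations of same-numbered arrays correlated at 0.104, -0.028, 0.028, 0.040 and 0.047, and 3 of 10 arrays correlated best with their own number. These weak values do not decide whether the numbers pair the arrays. The main fit had no block because the labels state no pairing, a choice made before the data were examined. The 3 rescalings moved the median difference by -0.018, -0.023 and -0.014. Without both Jam2+ replicate 1 and Jam2- replicate 6, 0 genes passed and 1279 had an unadjusted p under 0.05. What signal over background limits was not examined, as levels could not be tied to genes.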

Other observations

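The tests in this part were chosen after the data were seen. The hypothesis tested first was that values are displaced against the ID column. In windows of 300 IDs, 10 of the 17 windows within the last 5562 IDs fitted best at an offset of 5562 rows, and 0 of 137 windows of the table fitted best in place. At that offset, 7 of 7 pairs of identical rows with 1 gene each fell on the same gene. The 0 of 158 pairs found as deposited cover the whole table; the rows of this part held 0 such pairs as deposited, so no count over the same rows can be set beside the 7. The median of ribosomal protein rows there was 12.16 (23 rows) and that of receptor rows 3.63 (137 rows). For the other IDs the model gave offsets of up to 7296. It let the offset only grow along the table, so the growth in its placements is no test. Counting the last 5562 IDs, 25016 of 41345 IDs were placed with a posterior above 0.9. Among the other IDs so placed, NADH dehydrogenase, proteasome and splicing rows reached a median of 9.56 and receptor rows 3.70. Ribosomal protein rows reached only 8.19, and keratin and defensin rows stayed at 5.97, so the placement there is less certain. The offset was first noticed from gene family levels, so these levels are no independent test. The ID steps use no family, but the offset was set from them in windows, so they are no independent test either. Among the checks given here, only the identical rows entered neither step. They cover only the last 5562 IDs and leave the placement of the other IDs untested.

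With rows so displaced, gene identities are inferred, and the following list results are a hypothesis on that inference. Of 15473 genes placed, 0 passed in limma, and 729 had an unadjusted p under 0.05 where chance gives 774. Camera at its preset correlation called 4 of 27 lists, and 0 of them held with an estimated correlation. The adjusted p with an estimated correlation was 0.230 for the megakaryocyte and platelet list, 0.257 for mature neutrophils and 0.703 for both the G2/M and DNA replication lists. Jam2+ minus Jam2-, the mean difference was -0.23 for the megakaryocyte and platelet list, with 13 of 15 members below 0, and -0.72 for the mature neutrophil list, with 7 of 7 below 0. It was 0.24 for the G2/M list, with 16 of 16 members above 0, and 0.15 for the DNA replication list, with 17 of 21 above 0. Without Jam2+ replicate 5 the G2/M difference was 0.12 and the DNA replication difference 0.08; without Jam2- replicate 6 the G2/M difference was 0.15. The neutrophil list means of the Jam2- arrays were spread, with an SD of 0.60 against 0.02 in Jam2+ arrays. The granulocyte and monocyte progenitor list differed by 0.02, with 7 of 12 members above 0, and 6 further blood cell lists (erythroid, macrophage, B, T, NK and mast cell) by -0.06 to 0.07; none of these 7 was called. Notch and lymphoid priming lists differed by 0.01 and -0.02 and were not called. The displaced row for Jam2 differed by 0.03 with a standard error of 0.186 (limma adjusted p = 0.997).

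These list calls may come from genes that vary together or from chance. With an estimated correlation 0 lists were called, and fry called 0. Of 100 splits of the arrays, the real one included, 31 gave at least its 4 lists, and the highest other gave 7. The megakaryocyte and neutrophil lists had the smallest p that exact permutation allows, 0.00794, which became 0.107 when adjusted over the lists. With so few lists at that smallest p, the adjusted value could not fall under 0.05, so it does not decide. The largest differences of other splits, 0.23 and 0.72 in size, nearly equalled the real ones. Each came from exchanging a pair of near-equal arrays between the groups. For megakaryocytes these were Jam2+ replicate 4 and Jam2- replicate 6, both at 8.90. For neutrophils they were Jam2+ replicate 5 (5.35) and Jam2- replicate 6 (5.36). The near-equality therefore does not bear on chance. Under 16 of 19 alternatives 3 to 5 lists were called, among them 3 without Jam2+ replicate 5 and 5 under an earlier row placement. The others gave 7 lists without Jam2+ replicate 2 and 0 with an estimated correlation or fry. All 4 lists were called by camera at its preset correlation under both placements. With 1 array left out, the megakaryocyte difference ran from -0.26 to -0.20 and the neutrophil difference from -0.89 to -0.52. The earlier placement added the NK cell list (camera adjusted p = 0.0319). Both placements set the last 5562 IDs alike. Among the remaining IDs placed by both, 90.8% fell on the same row. In the earlier placement the differences were -0.43 for neutrophils, -0.18 for megakaryocytes, 0.17 for G2/M and 0.09 for DNA replication.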
